A study of Mus musculus with 21 samples.

How the data were processed

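Messenger RNA was sequenced in 21 libraries from the ventral pons of female CX3CR1GFP/wt mice, which carry a green fluorescent protein in place of 1 copy of a microglial receptor gene. The labels give 7 groups of 3 libraries: the unoperated pons at day 0, and the lesion and contralateral sides at days 7, 14 and 30 after the right facial nerve was cut at 8 weeks of age. Libraries were made from 300 ng of total RNA with a stranded mRNA kit and read as 50-base single reads.

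The authors called bases with CASAVA 1.8.2, aligned reads with Rsubread at default settings to GRCm38.p4 with a GENCODE mouse annotation, and counted reads per gene symbol with featureCounts. The strand setting of the counting is not stated, so reads of a gene that overlaps another on the opposite strand may be shared between them. The deposited count table holds raw counts for 45664 gene rows, 1 column per library. The deposited voom matrix holds log2 CPM (counts scaled by the library total) of 22294 genes, after the authors removed genes without a count and then those whose summed count did not exceed the 32nd percentile. For the 22269 of these matched to the counts by symbol the log2 values were recomputed with TMM factors and differed by at most 5e-11. Of its gene rows 27 carry symbols turned into dates, and 2 of these occur 2 times. Every per-sample column was used. At day 30 the side letters in the count column names are opposite to the sides in the sample labels. The sample descriptions assign each of these columns to the labelled side, and this assignment was followed. The direction of every day 30 result rests on it. With it, the voom column of each of the 21 libraries correlated best with the count column of the same sample.

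The same filter was applied here: 32815 genes had a count, and a summed count above 29 left 22294 genes, the lowest of them with 30 counts. Tests used edgeR 4.0.16 in R 4.3.3 (TMM factors, robust quasi-likelihood F-test, 1 coefficient per group, all 21 libraries in 1 model). Each comparison was adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The study's second threshold, an absolute log2 change of 1.7, was an alternative. Log2 differences are printed with their standard error from the same test, and CPM as the mean with the SD of 3 libraries. All tests were two-sided. An exact test of 3 against 3 libraries cannot give a p below 0.1, so the spread was estimated over all groups.

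Comparisons were lesion against contralateral side on each day, each operated group against day 0, and the difference between days of the lesion effect (an interaction contrast). In addition, 28 gene lists, each a process or a cell type, were fixed before the data were examined, as were the comparisons, the tests and the alternatives. Lists were tested with limma 3.58.1 (camera) at a preset correlation between genes of 0.01, adjusted over the 28 lists of a comparison. Because other groupings of the libraries also gave many calls at the preset value, list results are printed with the adjusted p from a correlation estimated per list. Tests of lists on the difference between days were added after the data were seen. Contrasts between contralateral groups of different days were added then too. Counts of called list members are given over all genes tested and "adjusted over the list alone".

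Named genes followed a fixed rule. For lesion against contralateral side these were the 10 rising and 10 falling genes with the largest change among called genes with at least 1 CPM on average and with the 3 lesion libraries all above or all below the 3 contralateral ones. For the other comparisons 5 rising and 5 falling genes were taken by the same rule, without the last condition for differences between days. The rule added the 2 to 4 members of each described list with the smallest adjusted p and 12 marker genes. Symbols of predicted or clone-based genes were counted and not named. Positions are from a GENCODE annotation of GRCm38, where all 384 genes looked up were found by symbol. Of these, 27 share exon bases with a gene on the same strand and 83 lie opposite a gene on the other strand.

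Left and right libraries of a day carry matching replicate numbers in the labels. After group means were removed, the correlation across genes of left and right libraries with the same number ran from 0.26 to 0.4 at day 7, from -0.03 to 0.34 at day 14 and from 0.27 to 0.32 at day 30. The labels do not state that equal numbers mark the same animal, and the day 14 correlations fit this less well. A block for replicate number, called a block for animal below, was run as an alternative on all days. For single genes and lists it is given beside results of days 7 and 30 where it changes a call. Counts of genes with it are given for day 14 and for differences between days too. Other alternatives were DESeq2 1.42.0, limma-voom, limma on the deposited log2 matrix, DESeq2's size factors, 2 other filters, a fit of only the groups compared, and each library left out in turn. For the contralateral against day 0 counts, thinning of the day 0 libraries and offsets for GC content and length were added after the data were seen.

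On simulated data made from these counts, 87 of 100 genes changed by a factor of 2 and 70 of 100 changed by a factor of 1.5 were recovered, with 8 false calls among 165. The changed genes were drawn from those with at least 1 CPM on average, so the recovery does not cover rarer transcripts. A contrast without simulated change gave 0 calls, the raised list had an adjusted p of 1.7e-63, and 0 of 28 lists without a raised gene were called. Simulated genes were drawn independently of each other, so these list results do not cover correlation between genes. In the real libraries, other groupings for lesion against contralateral side gave medians of 12, 11 and 10 lists at days 7, 14 and 30 (preset correlation). These groupings keep part of the lesion effect, so the medians are not counts of false calls. Depth limits precision for rare transcripts: where 1 group had 0 counts, the fold is given against a floor of 3 counts over the group, which covers counting error only. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Pathway and time-series clustering results of the study were not used here. Some results are not reported here.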

Results

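Transcripts were counted in the ventral pons, the brainstem block that holds the facial nucleus, of female mice whose right facial nerve had been cut. The 7 groups of 3 libraries were the unoperated pons at day 0 and the lesion and contralateral pons at days 7, 14 and 30, and the counts are raw reads per gene symbol. Summed counts ran from 35874913 to 41448945 in the day 0 libraries and from 17358868 to 29827291 in the others. The female transcript Xist, opposite Tsix, was present at 149 to 308 CPM in every library, and the Y-linked Ddx3y reached at most 0.151 CPM. Mitochondrial transcripts made up 3.24% ± 0.309 of counts (SD, n = 3) at day 0 and 6.66% ± 0.547 in the contralateral pons at day 30. In day 14 lesion replicate 2 they made up 2.81%, against 4.48% and 4.4% in the other lesion libraries of that day. The lesion was always on the right, and the contralateral and day 0 tissue always on the left, so lesion and side were not varied separately. Age (8, 9, 10 and 12 weeks) and sequencing lane also changed with the day, and day cannot be told apart from these.

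**Figure D1:**
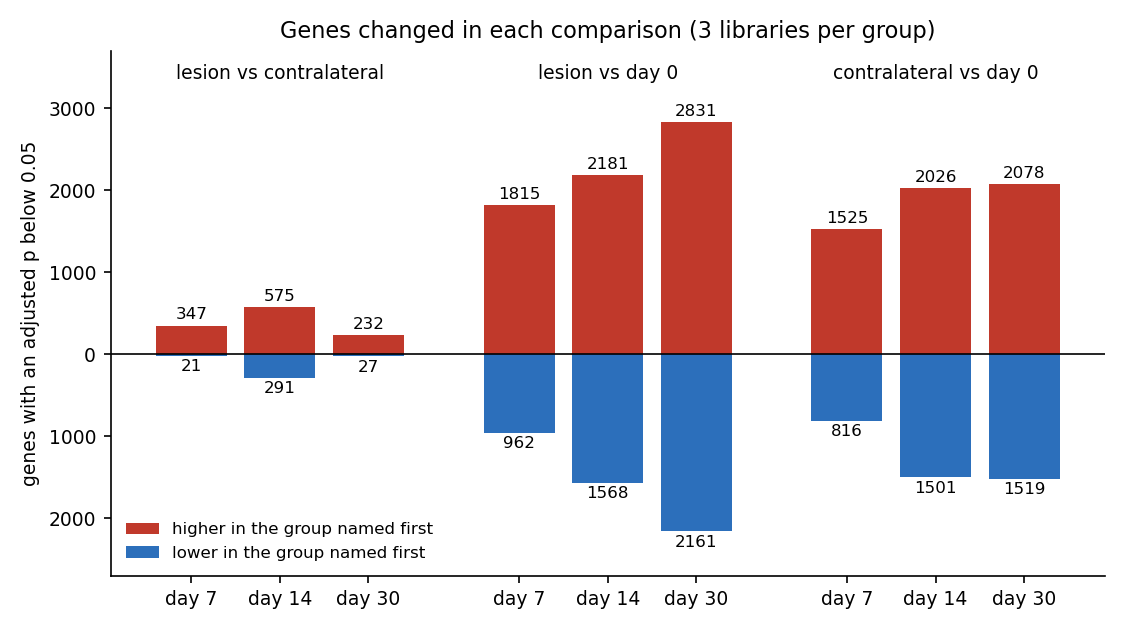
Number of genes with an adjusted p under 0.05 that were higher or lower in each of 9 comparisons (3 libraries per group). The contralateral pons differed from the day 0 pons at 2341, 3527 and 3597 genes, and the lesion side from the contralateral side at 368, 866 and 259.

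Lesion against contralateral side at day 7 asks which transcripts an axotomy changes in the pons that holds the cut neurons. Sprr1a, a small proline-rich protein made by regenerating neurons (GRCm38 chromosome 3, 92483952 to 92485895), rose by 9.46 ± 0.5 (log2 ± SE), from 0.316 ± 0.022 to 226 ± 64 CPM (SD, n = 3 per side, adjusted p = 2.6e-08). The stress transcription factor Atf3 (chromosome 1, 191170296 to 191218039) rose by 5.75 ± 0.31, from 1.53 ± 0.16 to 82.6 ± 12 CPM (adjusted p = 2.1e-08). The neuropeptide genes Gal and Npy rose by 4.37 ± 0.35 and 3.27 ± 0.43 (adjusted p = 2.2e-06 and 4e-04), and Gpr151, an orphan receptor gene, by 5 ± 0.35 (1.7e-08). The VIP receptor gene Vipr2 fell by 2.14 ± 0.26, from 7.94 ± 0.72 to 1.76 ± 0.65 CPM (adjusted p = 2.4e-05), and the potassium channel gene Kcnj14 fell by 1.79 ± 0.19 (4.3e-06).

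In the day 7 comparison 347 genes were higher and 21 lower on the lesion side. For every gene named here as past the threshold all 3 lesion libraries lay on 1 side of the contralateral range, which the naming rule required of the largest changes. Of 21 axotomy response genes 14 rose (17 adjusted over the list alone), with a median log2 difference of 0.69 and adjusted p = 1.5e-06 with an estimated correlation. Among them were the growth cone gene Gap43 (0.54 ± 0.09, adjusted p = 0.00083) and the GDNF receptor gene Gfra1 (1.47 ± 0.11, 8.6e-08), which lies opposite Gm16277. Of 14 motor neuron genes 2 fell, the lectin gene Chodl (-1.38 ± 0.3, adjusted p = 0.026) and the neurofilament gene Nefl (-0.22, 0.042), whose exons overlap those of Nefm on the other strand. Adjusted over the list alone 6 fell and 1 rose. The motor neuron median was -0.28 with adjusted p = 0.074 with an estimated correlation. Chat, the acetylcholine synthesis enzyme, stood at 17.7 ± 6.7 against 31 ± 5 CPM (-0.79 ± 0.22, adjusted p = 0.13); with a block for animal the adjusted p was 6e-05, by DESeq2 0.033, by limma-voom 0.023 and without lesion replicate 3 0.0011.

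Microglial genes were higher on the lesion side at day 7. Of 16 homeostatic microglia genes 9 rose (11 adjusted over the list alone), with a median of 0.49 and adjusted p = 0.00016 with an estimated correlation. They included Tmem119 (0.72 ± 0.09, from 22.5 ± 0.58 to 37 ± 2.7 CPM, adjusted p = 1.3e-05) and Olfml3 (0.77 ± 0.09, 4.3e-06). Of 20 activation genes 8 rose (9 adjusted over the list alone), with a median of 0.4 and adjusted p = 0.0016 with an estimated correlation. They included the growth factor gene Csf1 (0.77 ± 0.08, 4.5e-07) and the lipid receptor gene Trem2 (0.75 ± 0.11, 0.00012). Which cells of the bulk pons made these transcripts was not measured, so a listed gene need not have risen in microglia. Complement had 5 of 18 genes higher (6 adjusted over the list alone), a median of 0.38 and adjusted p = 0.00033 with an estimated correlation. C1qa, a chain of the first complement component, rose by 0.94 ± 0.08 from 47.2 ± 3.2 to 90.6 ± 12 CPM (adjusted p = 1.2e-08). Of 20 lysosomal genes 8 rose (9 adjusted over the list alone), with a median of 0.17 and adjusted p = 0.00016 with an estimated correlation, led by the protease gene Ctss (1.04 ± 0.08, 9.6e-10). Aif1, which encodes the microglial protein Iba1, rose by 0.78 ± 0.14 (adjusted p = 0.0016). Mki67, a gene of dividing cells, stood at 1.36 ± 0.5 against 1.21 ± 0.07 CPM (adjusted p = 1).

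Of 19 reactive astrocyte genes 4 rose at day 7 (5 adjusted over the list alone), with a median of 0.23 and adjusted p = 0.00011 with an estimated correlation. They included the hyaluronan receptor gene Cd44 (1.81 ± 0.15, 7.6e-08) and the protease inhibitor gene Timp1 (2.72 ± 0.26, 1e-07). Gfap, the astrocyte filament gene, stood at 930 ± 100 against 795 ± 170 CPM (0.23 ± 0.16, adjusted p = 0.95, and 0.027 with a block for animal). Of 17 cytokine and chemokine genes 2 rose, Ccl2 (4.25 ± 0.63, 0.00013) and Ccl7 (2.94 ± 0.43, 0.00012), and 7 did adjusted over the list alone, with a median of 1.09 (1.03 with Tnf, absent from the contralateral libraries, at its bound) and adjusted p = 0.002 with an estimated correlation. Of 20 apoptosis genes 3 rose (5 adjusted over the list alone), with a median of 0.17 and adjusted p = 0.00057 with an estimated correlation, led by the death gene Pmaip1 (1.75 ± 0.2, 1.2e-06). Of 19 antigen presentation genes 1 rose, the class I gene H2-D1 (0.34 ± 0.08, 0.01), and 4 did adjusted over the list alone, with a median of 0.34 and adjusted p = 0.0043 with an estimated correlation. The interferon response median was 0.76, with 2 of 27 genes higher (6 adjusted over the list alone) and adjusted p = 0.14 with an estimated correlation. Lymphocyte genes had a median of 0.45 (0.42 with Cd8b1, absent from the contralateral libraries, at its bound) and 0 of 17 past the threshold (0 adjusted over the list alone), and adjusted p = 0.33 with an estimated correlation. Cholesterol synthesis had a median of 0.07, 2 of 17 genes higher (3 adjusted over the list alone) and adjusted p = 0.36 with an estimated correlation. Choroid plexus genes had a median of 2.39, 0 of 9 past the threshold (5 adjusted over the list alone) and adjusted p = 0.4 with an estimated correlation. Ttr, the most abundant choroid plexus transcript, reached 4350 CPM in lesion replicate 3 and 3.61 to 878 CPM in the other 20 libraries, and without that replicate the list adjusted p was 0.91.

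Of the day 7 genes named above, Chodl missed the threshold without lesion replicates 1 or 2 or contralateral replicate 2 (adjusted p = 0.13 each), without contralateral replicate 3 (0.077) and with a block for animal (0.08). Nefl missed it without lesion replicates 1, 2 or 3 (0.15, 0.15 and 0.065) or contralateral replicates 2 or 3 (0.35 and 0.077) and in 3 other settings (0.055 to 0.1), and H2-D1 did so without lesion replicates 1 or 2 (0.11 and 0.058) or contralateral replicate 3 (0.072) and in the deposited log2 matrix (0.069). Npy missed it in a fit of only the groups compared (0.056).

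**Figure D2:**
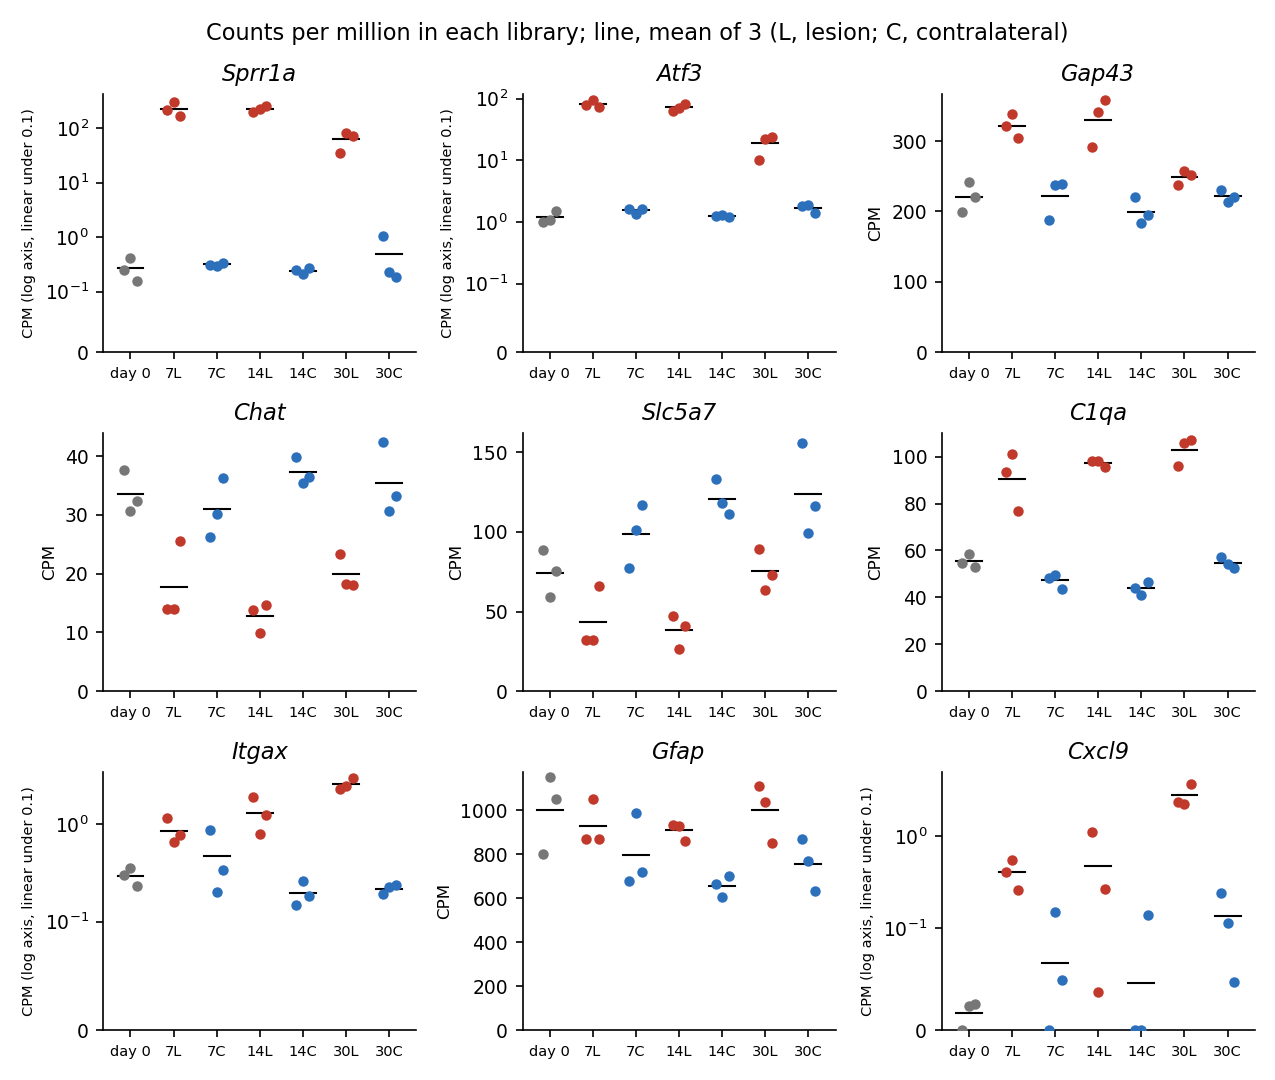
CPM (log axis, linear under 0.1 for Sprr1a, Atf3, Itgax and Cxcl9) of 9 genes in each of the 21 libraries, by day and side, with a line at the mean of 3. Sprr1a averaged 226 CPM on the lesion side at days 7 and 14 and 63.3 CPM at day 30, while Itgax and Cxcl9 averaged 2.56 and 2.76 CPM there at day 30.

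Lesion against contralateral side at day 14 asks the same at the next time point. Sprr1a rose by 9.83 ± 0.52, from 0.242 ± 0.033 to 226 ± 27 CPM (n = 3 per side, adjusted p = 1.8e-08), and Atf3 by 5.84 ± 0.32 (1.8e-08). Gal rose by 5.06 ± 0.36 (adjusted p = 5.2e-07) and Npy by 4.61 ± 0.45, from 5.87 ± 1.7 to 145 ± 19 CPM (1.5e-05). Chat (chromosome 14, 32408203 to 32465989) fell by 1.54 ± 0.22, from 37.3 ± 2.2 to 12.8 ± 2.5 CPM (adjusted p = 0.00062), and the choline transporter gene Slc5a7 (chromosome 17, 54273590 to 54299034) fell by 1.66 ± 0.3, from 120 ± 11 to 38.3 ± 11 CPM (0.0048).

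In the day 14 comparison 575 genes were higher and 291 lower on the lesion side. All 3 lesion libraries again lay on 1 side of the contralateral range for every gene named as past the threshold. Vipr2 fell by 2.6 ± 0.26 (adjusted p = 8.9e-07) and Kcnj14 by 1.94 ± 0.19 (7.4e-07). Of 14 motor neuron genes 6 fell, among them Chodl (-1.63 ± 0.3, 0.0049), and the filament gene Prph rose (0.83, 0.021). Adjusted over the list alone 8 fell and 1 rose. The motor neuron median was -0.25 with adjusted p = 0.1 with an estimated correlation. Of 21 axotomy response genes 13 rose (17 adjusted over the list alone), with a median of 0.67 and adjusted p = 2e-05 with an estimated correlation. They included Gap43 (0.73 ± 0.09, 1.5e-05) and the tubulin gene Tubb2b (0.97 ± 0.08, 1.6e-08). Of 20 apoptosis genes 4 rose (4 adjusted over the list alone), with a median of 0.2 and adjusted p = 0.0045 with an estimated correlation. They included Pmaip1 (2.14 ± 0.19, 1.8e-08). Cholesterol synthesis had a median of 0.1, 4 of 17 genes higher (6 higher and 1 lower adjusted over the list alone) and adjusted p = 0.3 with an estimated correlation. The mevalonate enzyme genes Mvd and Mvk rose by 0.57 ± 0.09 and 0.47 ± 0.08 (adjusted p = 9.5e-05 and 0.00057).

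Microglial lists were higher again at day 14. Of 16 homeostatic genes 8 rose (13 adjusted over the list alone), with a median of 0.57 and adjusted p = 0.00072 with an estimated correlation. They included Siglech (0.9 ± 0.09, 2.5e-07). Of 20 activation genes 10 rose (15 adjusted over the list alone), with a median of 0.62 and adjusted p = 0.0011 with an estimated correlation. They included Trem2 (0.88 ± 0.11) and the phagosome gene Cd68 (0.91 ± 0.14, 0.00019). Aif1 rose by 1.4 ± 0.15 (adjusted p = 3.8e-07) and the fractalkine receptor gene Cx3cr1, opposite Gm33858, by 0.75 ± 0.15 (0.004). Of 18 complement genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.3 and adjusted p = 0.0064 with an estimated correlation. C1qa (chromosome 4, 136895917 to 136898803) rose by 1.15 ± 0.08, from 43.8 ± 2.7 to 97.3 ± 1.3 CPM (1.4e-10), and the complement inhibitor gene Cd55, opposite Gm16083, fell (-0.49 ± 0.14, 0.045). Of 20 lysosomal genes 9 rose (10 adjusted over the list alone), with a median of 0.18 and adjusted p = 0.00072 with an estimated correlation, led by Ctss (1.24 ± 0.08, 3e-11). Mki67 stood at -0.31 ± 0.26 (adjusted p = 0.56).

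Antigen presentation had 6 of 19 genes higher at day 14 (12 adjusted over the list alone), with a median of 0.56 and adjusted p = 0.0013 with an estimated correlation. The class I genes H2-D1, B2m and H2-K1 rose by 0.56 ± 0.08, 0.7 ± 0.11 and 0.62 ± 0.11 (adjusted p = 1.4e-05, 0.00086 and 0.0013). Of 17 cytokine and chemokine genes 5 rose (7 higher and 1 lower adjusted over the list alone), with a median of 1.22 and adjusted p = 0.0084 with an estimated correlation. They included Ccl7 (3.82 ± 0.45, 3.4e-06) and Ccl2 (3.9 ± 0.61, 0.00019). Of 19 reactive astrocyte genes 5 rose (6 adjusted over the list alone), with a median of 0.31 and adjusted p = 0.0011 with an estimated correlation. They included Cd44 (2.12 ± 0.16, 7.4e-09) and Serpina3n (1.58 ± 0.15, 3.3e-06). Gfap stood at 909 ± 40 against 657 ± 48 CPM (0.47 ± 0.16, adjusted p = 0.13). The interferon response median was 0.87, with 3 of 27 genes higher (10 adjusted over the list alone) and adjusted p = 0.29 with an estimated correlation. Lymphocyte genes had a median of 0.6, 1 of 17 higher (3 adjusted over the list alone) and adjusted p = 0.16 with an estimated correlation. Pan-neuronal genes had a median of -0.08, 1 of 17 lower (3 adjusted over the list alone) and adjusted p = 0.29 with an estimated correlation. Endothelial and mural genes had a median of -0.1 and adjusted p = 0.34 with an estimated correlation.

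The count of 866 genes at day 14 was 1898 with a block for animal (939 lower), 2000 without lesion replicate 1 (912 lower), 439 without lesion replicate 2 (51 lower), 482, 457 and 500 without contralateral replicates 1, 2 and 3, 499 in the deposited log2 matrix and 426 in a fit of only the groups compared. Cd55 and Prph were chosen for naming after their values were seen, and neither was refitted without single libraries.

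Lesion against contralateral side at day 30 asks what remained a month after the cut. Sprr1a and Atf3 were still higher, by 6.96 ± 0.5 (from 0.491 ± 0.49 to 63.3 ± 25 CPM, n = 3 per side, adjusted p = 2.4e-06) and 3.45 ± 0.32 (2.2e-05). Genes of activated microglia and of T cells rose: the integrin gene Itgax by 3.52 ± 0.4, from 0.218 ± 0.022 to 2.56 ± 0.37 CPM (adjusted p = 4e-06), and the chemokine gene Ccl5 by 4.88 ± 0.59, from 0.195 ± 0.21 to 6.05 ± 2.2 CPM (7.2e-05). Cxcl9, an interferon-induced chemokine (chromosome 5, 92321347 to 92328079), rose by 4.31 ± 0.7, from 0.133 ± 0.099 to 2.76 ± 0.81 CPM (adjusted p = 0.0014). The T-cell gene Cd8a had 45 counts over the 3 lesion libraries and 0 over the contralateral ones, at least 12.4-fold higher against a floor of 3 counts over the group (adjusted p = 0.003). Vipr2 fell by 2.01 ± 0.24 (3.3e-05) and Kcnj14 by 1.88 ± 0.18 (3.4e-06).

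In the day 30 comparison 232 genes were higher and 27 lower on the lesion side. The same held for all 3 lesion libraries in the genes named as past the threshold. Of 20 microglia activation genes 10 rose (12 adjusted over the list alone), with a median of 0.51 and adjusted p = 9.3e-05 with an estimated correlation. They included the cystatin gene Cst7 (4.27 ± 0.5, from 0.133 ± 0.052 to 2.68 ± 0.39 CPM, 5.9e-06), Clec7a (2.03 ± 0.26, 2.4e-05) and Trem2 (0.96 ± 0.11, 4.4e-06). Of 16 homeostatic genes 8 rose (13 adjusted over the list alone), with a median of 0.4 and adjusted p = 0.00026 with an estimated correlation. They included Siglech (0.5 ± 0.09, 0.0026) and Tmem119 (0.45 ± 0.09, 0.0083). Cx3cr1 stood at 0.46 ± 0.15 (adjusted p = 0.23, and 0.00083 with a block for animal). Of 18 complement genes 7 rose (8 adjusted over the list alone), with a median of 0.27 and adjusted p = 0.00017 with an estimated correlation. They included C1qa (0.91 ± 0.08, from 54.7 ± 2.3 to 103 ± 6 CPM, 2.6e-08) and the receptor gene C3ar1 (1.29 ± 0.18, 4.4e-05). Of 20 lysosomal genes 7 rose (9 adjusted over the list alone), with a median of 0.12 and adjusted p = 0.00011 with an estimated correlation, led by Ctss (1.09 ± 0.08, 1.6e-09).

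Immune lists were higher on the lesion side at day 30. Of 27 interferon response genes 9 rose (25 adjusted over the list alone), with a median of 1.41 and adjusted p = 0.007 with an estimated correlation. They included the antiviral genes Bst2 (1.52 ± 0.25, 0.0028) and Xaf1 (0.73 ± 0.13, 0.0013). Of 19 antigen presentation genes 5 rose (10 adjusted over the list alone), with a median of 0.48 and adjusted p = 9.3e-05 with an estimated correlation. They included H2-D1 (0.89 ± 0.07, 2.6e-08) and B2m (1.01 ± 0.11, from 120 ± 6.5 to 241 ± 32 CPM, 3.5e-05). Of 17 lymphocyte genes 6 rose (8 adjusted over the list alone), with a median of 1.76 (1.76 too with Cd8a and Cd8b1 at their bounds) and adjusted p = 5e-04 with an estimated correlation. They included the interleukin receptor gene Il2rb (2.52 ± 0.49, 0.0046). Markers of border tissue stood at medians of 0.37 for choroid plexus (0 of 9 past the threshold, and 0 adjusted over the list alone), 0.17 for meningeal fibroblasts and 0.09 for border macrophages. Erythrocyte genes stood at -0.22. Of 17 cytokine and chemokine genes 4 rose (9 adjusted over the list alone), with a median of 1.47 and adjusted p = 0.00097 with an estimated correlation. They included Ccl3 (2.65 ± 0.53, 0.006).

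Among neuronal and astrocyte lists at day 30, 6 of 21 axotomy response genes rose (10 adjusted over the list alone), with a median of 0.31 and adjusted p = 0.00025 with an estimated correlation. They included Gal (2.46 ± 0.36, 0.0016). Npy rose by 3.01 ± 0.45 (0.0021). Gap43 stood at 0.17 ± 0.09 (adjusted p = 0.71). Of 14 motor neuron genes 4 fell (9 adjusted over the list alone), with a median of -0.23 and adjusted p = 0.017 with an estimated correlation. They included Chodl (-1.56 ± 0.29, 0.011). Chat stood at -0.83 ± 0.22 (adjusted p = 0.11, and 6.7e-05 with a block for animal, 0.027 by DESeq2 and 0.019 by limma-voom). Of 19 reactive astrocyte genes 3 rose (5 adjusted over the list alone), with a median of 0.32 and adjusted p = 0.00019 with an estimated correlation, Timp1 (2.15 ± 0.27), Cd44 (1.39 ± 0.16, 1.5e-05) and Serpina3n (0.88 ± 0.15, 0.0034). Gfap (chromosome 11, 102887336 to 102900912) stood at 1000 ± 130 against 758 ± 120 CPM (0.4 ± 0.16, adjusted p = 0.54, and 2e-04 with a block for animal). Of 20 apoptosis genes 1 rose, Pmaip1 (1.37 ± 0.2, 0.00013), and 1 did adjusted over the list alone, with a median of 0.1 and adjusted p = 0.017 with an estimated correlation. Cholesterol synthesis had a median of -0.05 and 0 of 17 genes past the threshold (0 adjusted over the list alone; list adjusted p = 0.075, or 0.0051 and 0.046 without contralateral replicate 3 or lesion replicate 1, and 0.74 with an estimated correlation).

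The count of 259 genes at day 30 was 169 without lesion replicate 3, 154 without contralateral replicate 3 and 550 in a fit of only the groups compared, in which Atf3, Gal and Npy missed the threshold (adjusted p = 0.07, 0.063 and 0.055). Chodl missed it without lesion replicates 2 or 3 (0.063 and 0.069) or contralateral replicate 1 (0.051) and with a block (0.052), Tmem119 without contralateral replicate 2 (0.12), and Cxcl9, Ccl3 and Il2rb in the deposited log2 matrix (0.056, 0.07 and 0.14).

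**Figure D3:**
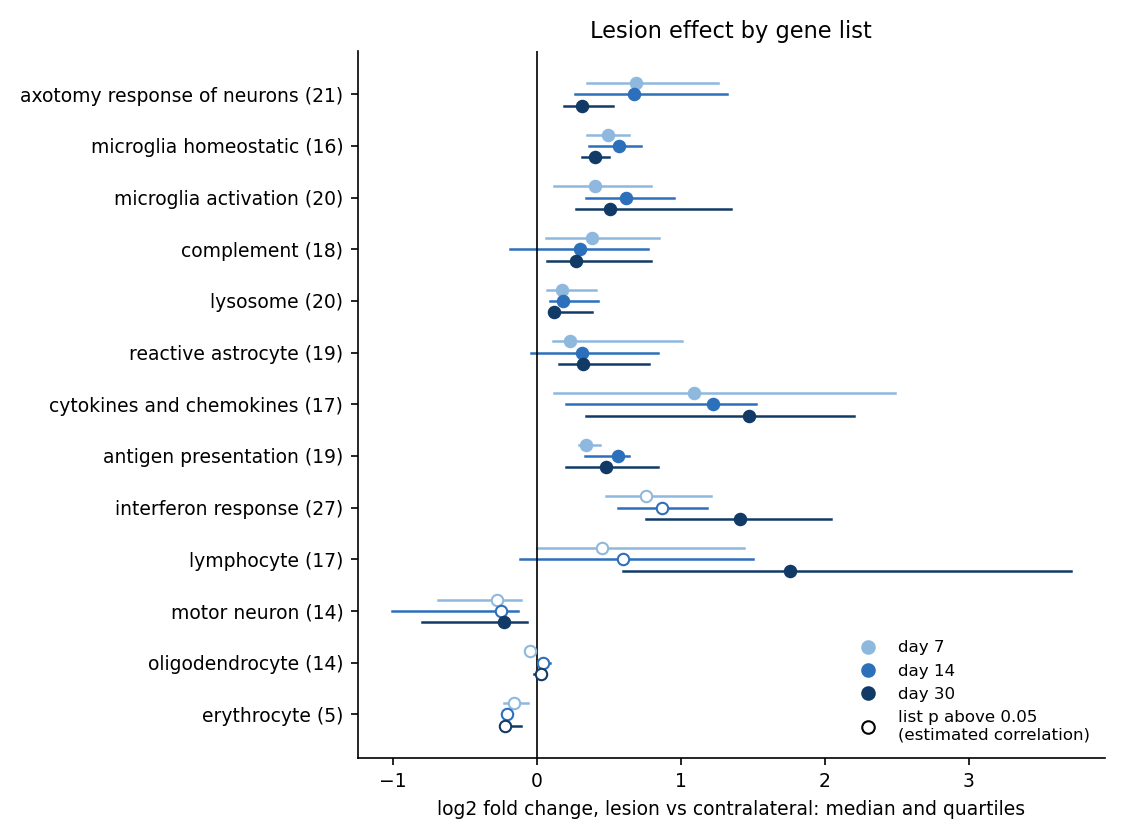
Median log2 difference between lesion and contralateral side, with quartiles, of 13 gene lists at days 7, 14 and 30 (3 libraries per side and day, open symbols where the list's adjusted p with an estimated correlation was above 0.05). Lymphocyte genes had medians of 0.45, 0.6 and 1.76, and axotomy response genes 0.69, 0.67 and 0.31.

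Several lists did not pass the test on any day, either at the preset or at an estimated correlation. Values without single libraries or with a block are at the preset correlation, at which other groupings of the libraries also gave many calls. For days 7, 14 and 30 in turn, the list adjusted p at the preset correlation was 0.33, 0.89 and 0.41 for 35 proliferation genes (0.038 at day 7 without lesion replicate 1), 0.99, 0.71 and 0.84 for immediate early genes, 0.79, 0.72 and 0.66 for astrocyte genes, 0.79, 0.28 and 0.33 for oligodendrocyte precursor genes, and 0.65, 0.72 and 0.53 for erythrocyte genes. It was 0.11, 0.72 and 0.71 for oligodendrocyte genes, with 0.0065 and 0.0011 at day 7 without lesion replicate 2 or contralateral replicate 3. It was 0.63, 0.32 and 0.71 for border macrophage genes, with 0.044 and 0.0023 at day 14 without lesion replicate 3 or contralateral replicate 1. Meningeal fibroblast genes had 0.99, 0.19 and 0.17, with 0.0026 at day 30 with a block for animal and 0.028 and 2.3e-06 at day 14 without lesion replicate 3 or contralateral replicate 1. Ependymal genes had 0.33, 0.58 and 0.71. Cerebellar neuron genes had 0.083, 0.077 and 0.065, with 0.021 and 0.0046 at days 7 and 30 with a block. They passed at day 7 without lesion replicate 1 (0.018) or contralateral replicates 2 or 3 (0.012 and 0.037), at day 14 without lesion replicates 2 or 3 (0.037 and 0.0018) or contralateral replicate 1 (0.003), and at day 30 without lesion replicates 2 or 3 (0.015 and 0.0033) or contralateral replicate 2 (0.026). Serotonergic neuron genes had 0.11, 0.84 and 0.065, and passed at day 7 without lesion replicate 1 (0.0057) or contralateral replicates 1 or 3 (0.00023 and 0.036) and at day 30 without lesion replicate 1 (0.035) or contralateral replicate 3 (0.0072). Monocyte and neutrophil genes had 0.17, 0.28 and 0.33, with 0.048 at day 14 without lesion replicate 2, and 0.0073 and 0.022 at day 30 without lesion replicate 3 or contralateral replicate 1. Of their 13 genes the neutrophil growth factor receptor gene Csf3r rose on each day (0.79 ± 0.13, 1.03 ± 0.13 and 1.2 ± 0.13). Another, Mmp9, went the other way and was called lower on each day.

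Across the 3 days 121 genes were higher and 13 lower on the lesion side each time. The 13 included Vipr2, Kcnj14, the protease gene Prss12, which lies opposite Gm35065, the serotonin receptor gene Htr3a and the secreted Wnt modulator gene Dkk3. Of the genes higher at day 7, 283 were also higher at day 14 (8.95 by chance, as n1 × n2 / N) and 133 at day 30 (3.61 by chance). Days 14 and 30 shared 152 higher genes (5.98 by chance). Lower genes were shared by days 7 and 14 in 16 cases (0.274 by chance), by days 14 and 30 in 19 (0.352) and by days 7 and 30 in 14 (0.0254), and 0 genes moved in opposite directions. Each day had its own contralateral libraries. Across all genes, which are not independent replicates, the effects correlated with Pearson's r of 0.3, 0.27 and 0.26 (Spearman's rho 0.2, 0 and 0.12) for days 7 and 14, 14 and 30, and 7 and 30. Over 15480 genes with at least 1 CPM r was 0.55, 0.47 and 0.56 (rho 0.32, -0.11 and 0.16).

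Whether the lesion effect itself differed between days was tested as an interaction of side and day. At day 30 it was smaller than at day 14 for 18 genes and smaller than at day 7 for 6 in the edgeR fit of all libraries, where 0 genes had a larger effect. Avpr1a, a vasopressin receptor gene (chromosome 10, 122448499 to 122453452), had effects of 1.88, 2.38 and 0.5 at days 7, 14 and 30 (difference between days 30 and 14 -1.88 ± 0.29, adjusted p = 0.0072). The kinase gene Uck2, which lies opposite Gm2453, had 1.01, 1.04 and 0.36 (-0.68 ± 0.1, 0.0049), and the integrin gene Itga7, opposite Mettl7b, 2.01, 2.06 and 0.97 (-1.09 ± 0.16, 0.0072). Against day 7 the effect of the tubulin gene Tubb6 was lower by day 30 (-0.95 ± 0.14, 0.0046), as was that of Uck2 (-0.65 ± 0.1, 0.0046). The axotomy response list had lower effects at day 30 than at day 14 (median -0.48, 4 of 21 genes past the threshold, 12 adjusted over the list alone, adjusted p = 0.025 with an estimated correlation) and than at day 7 (-0.35, 2 of 21, 11 adjusted over the list alone, 0.0038). The first of these list results missed the threshold without day 14 lesion replicates 1 or 3 (adjusted p = 0.082 and 0.058), day 14 contralateral replicate 3 (0.062) or day 30 lesion replicate 2 (0.052), with medians of -0.54, -0.45, -0.48 and -0.47. Of 40 splits, which permuted days within each side and did not keep left and right libraries of the same number together, 6 and 7 with the real one included gave at least 1 list of any kind, so chance is not excluded for the number of lists. In 10 splits that keep them together, too few for a share under 0.05, the lowest adjusted p of the axotomy list in another split was 0.75 and 0.47. Between days 14 and 7 edgeR called 0 genes (1320 with an unadjusted p under 0.05), and DESeq2 called 1.

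Uck2, Avpr1a and Itga7 were past the threshold between days 30 and 14 without each of the 12 libraries in turn, as were Tubb6 and Uck2 between days 30 and 7. Those counts of 18 and 6 rest on few libraries: without day 14 lesion replicate 1 the 18 were 994, of which 470 had a higher log2 effect at day 30, and they were 745 (418 higher) with a block for animal, 200 (71) by DESeq2, 331 (140) with only genes of sum 0 removed and 81 (32) in a fit of only the groups compared, but 4 without day 30 lesion replicate 1, 5 without day 14 contralateral replicate 2, 6, 8 and 10 without day 14 lesion replicates 2 and 3 and contralateral replicate 3, 8 and 9 without day 30 lesion replicates 2 and 3, and 6, 8 and 11 without day 30 contralateral replicates 1, 2 and 3; the 6 were 3 without day 7 lesion replicates 1 or 2 or contralateral replicate 2, 2 without day 7 contralateral replicate 3 or day 30 contralateral replicate 1, 10 without day 30 contralateral replicate 2 and 19 with a block for animal.

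**Figure D4:**
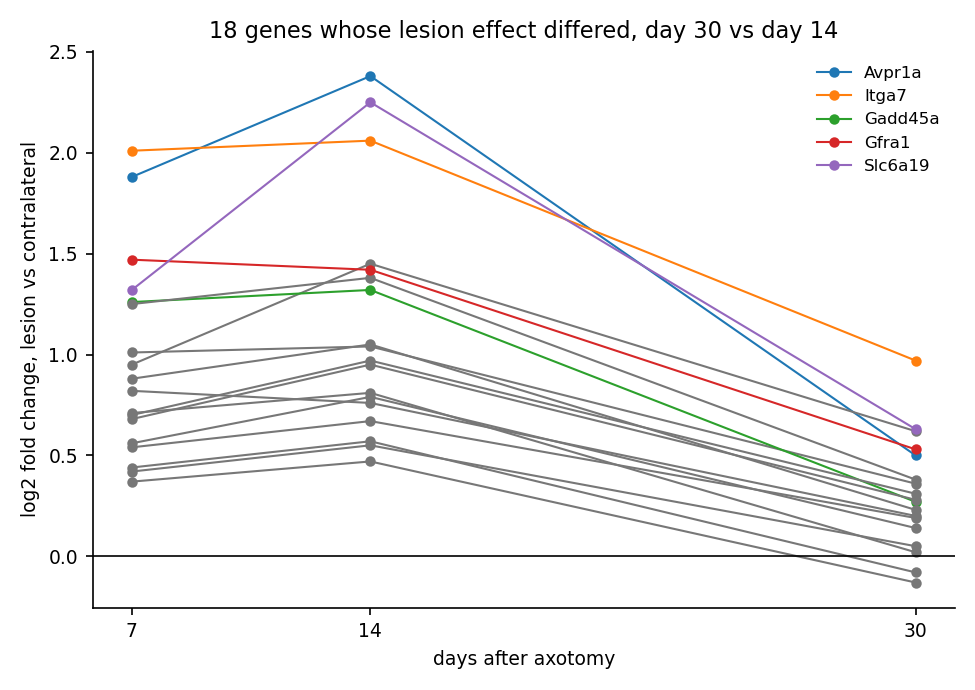
Lesion effect (log2 difference between lesion and contralateral side) at days 7, 14 and 30 of the 18 genes whose effect differed between days 30 and 14, 1 line per gene (3 libraries per side and day). All 18 lines end lower at day 30 than at day 14, as for Avpr1a from 2.38 to 0.5.

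The lesion side against the unoperated pons asks which genes differ between the injured right side and the left side of unoperated, younger mice. Sprr1a was higher by 9.63 ± 0.46, 9.63 ± 0.46 and 7.78 ± 0.48 at days 7, 14 and 30 (n = 3 per group, adjusted p = 3.4e-09 at day 7), and Atf3 by 6.1 ± 0.29, 5.9 ± 0.29 and 3.95 ± 0.3. C1qa was higher by 0.71 ± 0.08, 0.81 ± 0.08 and 0.89 ± 0.08 (adjusted p = 1.7e-07, 1.3e-08 and 2.8e-09). Vipr2 was lower at -2.04 ± 0.25, -2.22 ± 0.25 and -1.54 ± 0.24. At day 14 Chat fell by 1.39 ± 0.22 (adjusted p = 0.00038), and at day 30 Ccl5 rose by 4.85 ± 0.51 (1.7e-06).

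Against day 0 the lesion side had 1815 genes higher and 962 lower at day 7, 2181 and 1568 at day 14, and 2831 and 2161 at day 30. All 3 lesion libraries lay on 1 side of the day 0 range for the genes printed here as past the threshold. Gap43 rose by 0.55 ± 0.09 at day 7 (adjusted p = 0.00018) and stood at 0.18 at day 30 (0.17), and Gfap stood at -0.11, -0.14 and 0 (0.75, 0.63 and 1). Of these genes, 1632, 1933 and 2827 (58.8%, 51.6% and 56.6%) also differed the same way between the contralateral and day 0 pons, where 159, 304 and 411 would by chance. The chance numbers hold for independent comparisons, whereas these use the same 3 day 0 libraries, so part of the excess may come from the shared controls. Over 15480 genes the 2 effects correlated with r of 0.68, 0.61 and 0.77 (0.45, 0.46 and 0.46 in simulated data without a change), with a covariance of 0.0647, 0.0643 and 0.0824 against 0.0114, 0.0117 and 0.0116. Chat at day 7 (-0.9 ± 0.22, 0.011) missed the threshold without lesion replicate 2 (0.056) and in a fit of only the groups compared (0.1), and at day 30 (-0.74 ± 0.21, 0.02) without day 0 replicate 1 (0.064) or lesion replicates 2 or 3 (0.072 and 0.077). In a fit of only the groups compared the day 14 count of 3749 was 1682.

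The contralateral against the unoperated pons asks whether the side opposite the cut also differs from the same side of unoperated, younger mice. Atf3 and Chat did not pass the test there: Atf3 stood at 0.35, 0.06 and 0.49 at days 7, 14 and 30 (n = 3 per group, adjusted p = 0.72, 0.96 and 0.52) and Chat at -0.11, 0.15 and 0.08 (0.81, 0.69 and 0.85). Of 21 axotomy response genes 1, 3 and 1 rose and 0, 1 and 1 fell (list adjusted p = 0.96, 1 and 0.98 with an estimated correlation). The cholesterol synthesis enzyme gene Dhcr7 was lower, at -0.33, -0.34 and -0.38 (adjusted p = 0.00081, 0.00049 and 0.00015), as was the tight junction gene Cldn5, at -0.78, -1.22 and -0.96 (0.008, 0.00018 and 0.0012).

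Against day 0 the contralateral pons had 1525 genes higher and 816 lower at day 7, 2026 and 1501 at day 14, and 2078 and 1519 at day 30, with 1175 higher and 323 lower on all 3 days. For the genes printed here as past the threshold all 3 contralateral libraries lay on 1 side of the day 0 range. Among named genes, the largest rises that held without each library were in mitochondrial transfer RNA genes, with mt-Tc at 2.43 ± 0.26, 2.84 ± 0.26 and 3.25 ± 0.26 (adjusted p = 1.3e-05, 1.8e-06 and 3.5e-07), while the share of mitochondrial transcripts was 4.17%, 4.59% and 6.66% against 3.24% at day 0. The monooxygenase gene Fmo2 rose by 2.6 ± 0.31 at day 30, from 1.91 ± 0.55 to 11.5 ± 1.9 CPM (1.8e-05). The pericyte gene Vstm4 fell by 1.3 ± 0.11 at day 14, from 24.1 ± 2.7 to 9.78 ± 0.93 CPM (5.9e-09), and by 1.44 ± 0.11 at day 30 (9.1e-10). The channel gene Kcna3 fell by 1.49 ± 0.28 at day 7 (0.00074). The pituitary hormone genes Prl and Gh stood at 821 and 367 CPM in day 7 contralateral replicate 1 and at 287 ± 460 CPM (Prl, 6.49 ± 1.85, adjusted p = 0.037) over that group against 3.04 ± 4.6 at day 0; without this replicate their adjusted p was 0.37 and 0.39, and for Prl 0.12, 0.053 and 0.12 without day 0 replicates 1, 2 and 3.

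No list passed with an estimated correlation in the contralateral against day 0 comparisons. At day 7 4 of 17 pan-neuronal genes rose (6 adjusted over the list alone, median 0.11) and at day 14 7 (7 adjusted over the list alone, median 0.14), with adjusted p = 0.96 and 0.56 with an estimated correlation. The synaptic vesicle gene Snap25 rose by 0.52 ± 0.05, 0.53 and 0.38 (9.4e-08, 6e-08 and 6.9e-06), but with offsets for GC content and length its adjusted p was 0.16 at day 14 and 0.72 at day 30. Of 17 cholesterol synthesis genes 6, 8 and 5 fell (7, 11 and 7 adjusted over the list alone), with medians of -0.13, -0.22 and -0.18 and adjusted p = 0.96, 0.56 and 0.98 with an estimated correlation. They included Dhcr7 and Mvd (-0.44, -0.59 and -0.36). Of 14 oligodendrocyte genes 3, 7 and 6 fell and 1 rose on each day (7, 7 and 9 lower and 1 higher adjusted over the list alone), with medians of -0.17, -0.24 and -0.25 and adjusted p = 0.96, 0.56 and 0.98 with an estimated correlation. Cnp, a myelin enzyme gene opposite Dnajc7, fell by 0.3 at day 14 (0.001) and by 0.36 at day 30 (0.00015). Of 18 endothelial and mural genes 9 fell and 1 rose at day 30 (10 and 1 adjusted over the list alone), with a median of -0.29 and adjusted p = 0.98 with an estimated correlation. They included Pdgfrb, a pericyte receptor gene (-0.65, 3.7e-06). Of 10 cerebellar neuron genes 3 rose at day 7 (6 adjusted over the list alone), with a median of 1.28 and adjusted p = 0.96 with an estimated correlation. They included Neurod1 (1.75 ± 0.34, 0.0019), which shares exon bases with Cerkl and lies opposite Gm26755.

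The contralateral effects at the 3 days share the same 3 day 0 libraries. Over 15480 genes they correlated with r of 0.72, 0.77 and 0.74 for days 7 and 14, 14 and 30, and 7 and 30, where simulated data without a change gave 0.44, 0.45 and 0.45, with a covariance of 0.0593, 0.0678 and 0.0608 against 0.0114, 0.0116 and 0.0115. Higher genes were shared in 1265, 1475 and 1321 cases (139, 189 and 142 by chance) and lower genes in 393, 692 and 483 (54.9, 102 and 55.6 by chance), and part of this excess may come from the shared controls. Index sequences of 2 of the 3 day 0 libraries recur among day 7 libraries of the same lane number, so day 0 may have been sequenced in another run, which cannot be told apart from the group. The day 14 count of 3527 was 2242 without day 0 replicate 2, 2320 without contralateral replicate 2 and 1985 with offsets for GC content and length, and the day 7 count of 2341 was 1558 in a fit of only the groups compared.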

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

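The tests of depth, of GC content and length, of blood, of border tissue and of a smaller nucleus share, the list test without single libraries at an estimated correlation, the splits that keep pairs, the contrasts between contralateral days and the list tests on differences between days were chosen only after the results were seen, while the remaining splits and the other omissions of single libraries were planned. Most genes and lists here were taken up because the lesion effect on 1 day differed from that on another by an interaction test, and the contralateral against day 0 counts because of their size.

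The rise of axotomy response genes was smaller at day 30 than at day 14, with a median difference of -0.48 over 21 genes (adjusted p = 0.025 with an estimated correlation) and of -0.35 between days 30 and 7 (0.0038). A smaller share of the facial nucleus in the day 30 tissue stays open, as the whole cause and as a part. With an unchanged microglial response, a ratio of 0.46 between the axotomy response medians would need -0.33 for microglia activation and -0.31 for homeostatic genes. Those medians were 0.05 (quartiles -0.25 to 0.3) and -0.07 (quartiles -0.3 to -0.01). Whether the microglial response within the nucleus changed between these days was not measured, so the microglial values cannot decide it. The lesion effect on motor neuron genes differed by a median of 0.01 (quartiles -0.11 to 0.19). In the contralateral pons these genes stood 0.08 higher at day 30 than at day 14. Neither value shows a smaller share. Motor neuron genes also respond to the lesion, so they cannot decide it for the lesion side. Day 14 lesion replicate 2, with the lowest mitochondrial share on that side, is argued against, since without it the adjusted p with an estimated correlation was 0.016, while without 4 other libraries it was 0.052 to 0.082. A decline of the neurons' injury response between these days may contribute, as a hypothesis, while age and lane changed with the day and stay open. In other splits that keep left and right libraries of the same number together the lowest adjusted p of this list was 0.75 and 0.47, but 10 splits are too few for a share under 0.05.

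In 40 splits, the real one included, days were permuted within each side, so left and right libraries of the same number were not kept together and differences between days common to both sides enter. For days 30 and 14, 2 splits gave at least the real 18 genes (highest other 20), and for days 30 and 7, 3 gave at least the real 6 (highest other 34, several times the real count, which points to a structure of the samples, and days differ between contralateral groups too). These counts do not exclude chance. With an estimated correlation 6 and 7 splits gave at least the real 1 list of any kind, so chance is not excluded for the number of lists. Of splits that keep these together, 10 are too few for a share under 0.05: the real 18 and 6 genes stood against a highest other of 0 and 0, and the real 1 and 1 lists against 1 and 1, where the list of the other split was not the axotomy response (adjusted p = 1 and 0.47). Other splits of this kind mix libraries of both days within a group, so differences between days enter the spread there.

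Lymphocyte, interferon response and antigen presentation genes were higher on the lesion side at day 30, with medians of 1.76 (quartiles 0.6 to 3.71), 1.41 and 0.48. Residual blood is argued against by erythrocyte genes, whose median was -0.22 (Hbb-bs, the most abundant, 3.29 ± 1.3 against 3.85 ± 0.75 CPM). Border tissue stays open as a source. Choroid plexus genes stood at 0.37 (Ttr 31.3 ± 13 against 16.5 ± 8.7 CPM) and border macrophage genes at 0.09. Meningeal fibroblast genes stood at 0.17 (Igf2, which shares exon bases with Gm49394 and lies opposite Igf2os, 178 ± 28 against 166 ± 8.3 CPM). These medians lie below those of the immune lists above. A little added tissue moves rare transcripts more, so folds of lists at unlike levels cannot decide this. The meningeal list passed with a block for animal (adjusted p = 0.0026, against 0.063 to 0.76 in its other settings). The day 0 pons expressed 4 of 5 erythrocyte, 5 of 9 choroid plexus, 11 of 11 meningeal fibroblast and 6 of 7 border macrophage genes at 1 CPM or more. It expressed 0 of 17 lymphocyte genes at that level, and 0 genes of these lists are held by another list. T cells in the lesioned pons are a candidate source of the lymphocyte genes, as a hypothesis, and their location was not measured.

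Many genes differed between the contralateral and the unoperated pons, 2341, 3527 and 3597 at days 7, 14 and 30. Depth is argued against, since with day 0 thinned to the mean total of the operated libraries 2175, 3323 and 3398 genes passed, at the lowest 92.9% of the full count. GC content and length as the whole cause are argued against, since offsets for them left 1765, 1985 and 2515 genes (1339, 1399 and 1848 shared with the uncorrected calls), but as a part they stay open at 56.3% of the day 14 count. A separate run of the day 0 libraries, to which repeated index sequences of 2 of the 3 point, cannot be told apart from the group, and contralateral groups of different days, in different lanes, differed at 5, 91 and 31 genes. Age and a response of the opposite side to surgery may also contribute and were not tested apart from the run.

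The other genes whose effect was lower at day 30 than at day 14 were Uck2 (-0.68), Avpr1a (-1.88), Il4ra (-0.83), Itga7 (-1.09), Gadd45a (-1.06), Anxa2 (-1), Tubb2b (-0.66), Nrep (-0.64), Fads3 (-0.56), Mvd (-0.66), Serpinb6a (-0.79), Hn1 (-0.82), Cyb5r3 (-0.5), Stmn2 (-0.48), Gfra1 (-0.89), Mvk (-0.6), Tmem159 (-0.67) and Slc6a19 (-1.62), with adjusted p from 0.0049 to 0.03. Lower at day 30 than at day 7 were Tubb6 (-0.95), Uck2 (-0.65), Fads3 (-0.62), Itga7 (-1.04), Gadd45a (-0.99) and Gfra1 (-0.94), with adjusted p from 0.0046 to 0.04. Of these Uck2, Il4ra, Itga7, Gadd45a, Anxa2, Serpinb6a, Cyb5r3, Gfra1 and Tmem159 lie opposite another gene, and Hn1 was not found in the annotation. Without each of the 12 libraries in turn 3 of the 18 (Uck2, Avpr1a and Itga7) and 2 of the 6 (Tubb6 and Uck2) stayed past the threshold. Gadd45a lost its call between days 30 and 14 without day 30 lesion replicate 1 (0.055), as did Il4ra (0.052).

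At the preset correlation alone, microglia activation effects were higher by a median of 0.22 at day 14 than at day 7 (adjusted p = 0.018, and 0.9 with an estimated correlation) and by 0.16 at day 30 (0.0049, and 0.6). Antigen presentation effects were higher by 0.15 (0.048, and 0.9) and 0.14 (0.00038, and 0.19) in the same comparisons. Choroid plexus effects were lower, at -3.01 (5.1e-05, and 0.9) and -2.12 (0.0056, and 0.74), and without day 7 lesion replicate 3 the list adjusted p was 0.12 and 0.65. Cerebellar neuron effects were higher by 0.76 (0.00085, and 0.9) and 1.18 (0.001, and 0.6). Interferon response effects at day 30 were higher by 0.42 than at day 14 (0.00067, and 0.96) and by 0.57 than at day 7 (2.3e-07, and 0.62), and cholesterol synthesis effects lower, at -0.17 (0.00021, and 0.95) and -0.12 (1.1e-05, and 0.31). Endothelial and mural effects were higher by 0.15 at day 30 than at day 14 (0.016, and 0.95), and lymphocyte effects by 1.02 at day 30 than at day 7 (0.0013, and 0.24). Other splits did not exclude chance for these list counts at the preset correlation: 35, 35 and 20 of 40 splits, the real one included, gave as many as the real 4, 4 and 8 lists for days 14 and 7, 30 and 14, and 30 and 7 (highest other 14, 16 and 13). For genes between days 14 and 7 the real count was 0 and the highest other 1, so 40 of 40 splits gave as many. With an estimated correlation the real list counts were 0, 1 and 1, reached in 40, 6 and 7 of 40 splits with the real one included (highest other 1, 1 and 2).

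For the comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05, and the numbers of splits below include the real one. Every other split mixes libraries of both real groups unevenly. It keeps part of the real effect, and the rest enters the spread within its groups. Its counts are therefore not those of libraries without an effect, and a gap to the real count cannot decide on chance. The real lesion against contralateral counts were 368, 866 and 259 genes and the highest other split gave 2, 14 and 1. Splits that part all 3 pairs of libraries with the same number gave at most 1 gene at day 7 and 0 at day 30, and the other splits keep a pair on the same side. Lesion against day 0 gave 2777, 3749 and 4992 (highest other 0, 137 and 0) and contralateral against day 0 2341, 3527 and 3597 (highest other 47, 0 and 0). Lists at the preset correlation gave 14, 15 and 12 for lesion against contralateral side (highest other 17, 14 and 13, with 5, 1 and 2 of 10 splits as large) and 4, 3 and 3 for contralateral against day 0 (highest other 11, 12 and 15, with 8, 10 and 10 splits as large). With an estimated correlation the lesion against contralateral lists were 9, 9 and 12 and the highest other 1, 2 and 1.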

How the results depend on the processing

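The offsets for GC content and length, the thinning of day 0, the list tests on differences between days, the axotomy list without single libraries at an estimated correlation and the contrasts between contralateral groups were chosen only after the results were seen. Of 567 pairs of a named gene and a comparison, 461 were past the threshold. Over alternatives other than the omission of a library 4353 results for these pairs stayed on their side of the threshold. Of the rest 297 fell below it, 35 rose past it and 1 changed direction. Over the omission of each library 3223 stayed, 531 fell below and 8 rose past. Direction was compared only where the main or the alternative result was past the threshold. Of 252 pairs of a list and a comparison, 67 were past the threshold at the preset correlation. The corresponding results for the 252 were 1118, 66, 16 and 0, and 1899, 36 and 78 with 3 reversed. The cause was not tested for any of these unless stated. A block for animal was not run for comparisons with day 0, which has no contralateral partner, and genes a filter removed have no value under it. Lists were not tested with DESeq2, limma-voom, the deposited log2 matrix, the filter on a sum of 0 or a fit of only the groups compared, and Cd55 and Prph at day 14 were not run under any alternative. Low counts limit the lymphocyte genes, of which 0 of 17 reached 1 CPM in the day 0 pons.

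The study's second threshold, an absolute log2 difference of 1.7, left 68, 102 and 65 genes for lesion against contralateral side at days 7, 14 and 30, 178, 224 and 275 for lesion and 75, 98 and 100 for contralateral against day 0, 1 for the effect at day 30 against day 14 and 0 against day 7, because it removes smaller differences by construction. With a block for animal the genes were 1898 at day 14 (959 higher and 939 lower, 467 at day 7 and 372 at day 30, within 1.5 times), and 1, 745 and 19 for differences of effect between days 14 and 7, 30 and 14, and 30 and 7, where 418 of the 745 had a higher log2 effect at day 30. DESeq2 gave 1, 200 and 29 for these differences, a filter on genes with a sum of 0 alone 2, 331 and 32, and a fit of only the groups compared 81 and 16 for the last 2. The deposited log2 matrix gave 499 genes at day 14 and 6 for days 30 and 14. A fit of only the groups compared gave 426 (333 higher and 93 lower) and 550 at days 14 and 30, 1682 for lesion day 14 and 1558 for contralateral day 7 against day 0, and the GC and length offsets 1985 for contralateral day 14. The cause was not tested.

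With each library left out in turn, lesion against contralateral counts ran from 273 to 335, 439 to 2000 (388 higher and 51 lower, to 1088 and 912) and 154 to 213 at days 7, 14 and 30 and the contralateral day 14 against day 0 count from 2242 to 3860. Differences of effect ran from 0 to 1, 4 to 994 (470 of the 994 higher at day 30) and 2 to 10. List counts ran from 3 to 7 and 1 to 4 for contralateral days 14 and 30 against day 0 and from 2 to 6 for days 14 and 7. The correlation of effects ran from 0.26 to 0.3 (days 7 and 14), 0.21 to 0.28 (14 and 30) and 0.22 to 0.27 (7 and 30), and over genes with at least 1 CPM it was 0.55, 0.47 and 0.56. The cause was not tested.

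With an estimated correlation 9 and 9 lists passed at days 7 and 14, 0, 0 and 0 for contralateral against day 0, and 0, 1 and 1 for differences of effect. Fry gave 2 and 6 lists for contralateral days 7 and 14 and 0, 1 and 1 for differences of effect, and a block 7 lists for days 14 and 7. The erythrocyte list for contralateral day 7 against day 0 reversed without day 0 replicate 3 (adjusted p = 9.9e-06, range 9.9e-06 to 1 over the libraries left out), the interferon response list for days 14 and 7 without day 14 lesion replicate 1 (1.1e-06, range 1.1e-06 to 0.98) and the choroid plexus list, lesion effect, day 30 vs day 7, without day 7 lesion replicate 3 (0.65, range 1.6e-06 to 0.65). With an estimated correlation and 1 library left out the axotomy response list had adjusted p from 0.0099 to 0.082 for days 30 and 14 (past the threshold without 8 of 12 libraries) and from 0.0014 to 0.019 for days 30 and 7 (without 12 of 12). Clock, for contralateral day 14 against day 0, moved to -0.08 with the GC and length offsets (adjusted p = 0.41). The cause was not tested.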

Other observations

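The test on clock genes was chosen only after the result was seen. Other genes also rose on the lesion side. Ankrd1, a muscle ankyrin repeat gene also made by injured neurons, rose by 6.45 ± 0.54 at day 7, from 0.0508 ± 0.051 to 4.84 ± 0.77 CPM (n = 3 per side, adjusted p = 1.7e-08), and by 4.27 ± 0.46 at day 14 (7.7e-07). The annexin gene Anxa10 was higher by 4.85 ± 0.27, 5.24 ± 0.25 and 3.16 ± 0.27 at days 7, 14 and 30 (3e-12, 1.1e-13 and 2.6e-08). The phosphatase gene Ppef1 rose by 3.48 ± 0.27 at day 7 (1.3e-08) and 3.98 ± 0.27 at day 14 (5.9e-10), and the metalloprotease gene Adam8, which lies opposite Gm16201, by 3.08 ± 0.24 at day 7, from 2.77 ± 0.6 to 23.5 ± 3.6 CPM (1.3e-07). At day 14 the urate oxidase gene Uox rose by 4.01 ± 0.37 (3.8e-08).

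Genes of the circadian clock differed between the contralateral and the unoperated pons. Dbp, an output gene of the clock that lies opposite Sphk2, was higher by 1.13 ± 0.08, 1 ± 0.08 and 1.02 ± 0.08 at days 7, 14 and 30 (from 25.1 CPM at day 0 to 54.9, 50.3 and 50.8, n = 3 per group, adjusted p = 3.3e-10, 2.7e-09 and 1.4e-09). The repressor gene Nr1d2 was higher by 0.81 ± 0.06, 0.85 ± 0.06 and 0.84 ± 0.06 (1.3e-09, 5e-10 and 4.3e-10), and the activator gene Arntl, opposite Gm45355, lower at -0.68 ± 0.11, -0.74 ± 0.11 and -0.85 ± 0.11 (6.1e-05, 1.4e-05 and 1.9e-06).

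Day 0 tissue may have been taken at another time of day. Of 10 other clock genes 6 were past the threshold in the direction this predicts on all 3 days: Per3, Tef, which lies opposite Gm17597, Hlf and Ciart higher, and Npas2 and Nfil3 lower. Of these Npas2 missed the threshold at day 7 without contralateral replicate 2 (0.051), and Nfil3 at day 7 without day 0 replicates 2 or 3 (0.094 and 0.1) or contralateral replicates 1, 2 or 3 (0.08, 0.11 and 0.081). Per1 and Per2 passed in the predicted direction at days 14 and 30 but not at day 7 (adjusted p = 0.29 and 0.2). Nr1d1, opposite Thra, passed at day 7 only (0.55 ± 0.15, 0.031) and stood at 0.32 and -0.06 at days 14 and 30 (0.18 and 0.84). Clock went against the predicted direction at day 14 (0.27 ± 0.08, 0.016), and missed the threshold without day 0 replicate 2 (0.12) or contralateral replicate 2 (0.078). With the offsets for GC content and length Clock changed direction and missed the threshold. For the lesion side against day 0, 5 of the 10 genes passed in the predicted direction on all 3 days. The test, set for the contralateral side, required at least 6. The 3 days share the same 3 day 0 libraries, so their results are not independent. The labels give no time of day, a separate run of day 0 stays open, and a lasting effect of surgery on both sides was not tested.

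A large value rested on few libraries. The interferon-induced gene Cxcl10, opposite Art3, was at 17 CPM in day 30 lesion replicate 3 and 2.66 and 5.9 CPM in the other lesion libraries (4.38 ± 1.12 against day 0, adjusted p = 0.011, and 0.063 without that replicate).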
